A study of Homo sapiens with 12 samples.

How the data were processed

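RNA from HaCaT keratinocytes grown in 96-well plates was labelled as biotinylated cRNA and hybridised to 12 single-colour Affymetrix HG-U133 Plus arrays, per the labels' protocols. The groups were unstimulated, TNF+IFNg, TNF+IFNg with terbutaline and TNF+IFNg with GW9508, with 3 arrays each. Nothing in the labels says that the triplicate wells came from separate cultures on separate days, so p-values measure the spread between these wells, which may be technical.

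The deposited values are a linear intensity per probe set and array, made with MAS5 per the submitters' processing notes. Its version and scaling target are not given in the sources used here. The 54675 probe sets had deposited intensities from 0.0168 to 20992. Array medians differed by a factor of 1.64, above the limit of 1.25 set for scaling, so each array was scaled to the mean of the array medians, 18.2. An offset of 3.18, the 20th percentile of all scaled signals, was added before log2, which shrinks the fold changes of dim genes. Names came from the platform's gene table, in which 41091 probe sets had 1 gene, 1801 had several and 11721 are unnamed here, and 62 were controls. Only probe sets with 1 gene were used in the main comparisons. Probe sets with a mean log2 value below 3.66, the 40th percentile, were left out, and each gene was represented by its probe set with the highest mean, which left 14056 genes. The sources used here name no genome build, so positions are given as chromosomes only. The number of arrays limits the precision. The median SE of a log2 fold change was 0.14.

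A model without covariates was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend and 8 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 14056 genes of a comparison, and genes below 0.05 were called. The comparisons were TNF+IFNg against unstimulated, each compound against TNF+IFNg, and GW9508 against terbutaline. Of 36 gene lists, 31 of pathways and 5 of markers of other cell types, the 33 with at least 5 genes tested were compared with all other genes by camera with a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, which tests whether the genes of a list moved on balance one way without comparing them with other genes. For the slopes, correlation and covariance across genes, shared TNF+IFNg arrays were allowed for by 20 simulations of unchanged groups. All 12 arrays were redrawn in each from the fitted means with independent noise. Counts of overlapping genes were not corrected for the shared arrays.

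The groups, the comparisons and their tests, the 36 lists, most other settings tried and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap between the groups, and up to 4 called members with the largest change of each list that was called or had at least 3 called members. Uncharacterised symbols were passed over. CCL5, CCL17, CXCL8, CXCL9, CXCL10, CXCL11, CCL20, IL6, FFAR1 and FFAR4 were always given, and 1 further receptor gene is not analysed here. The rule gave 521 results, 507 of them called, and the text names only part of them, chosen after the values were seen. That choice favoured genes whose probe sets pointed the same way. Of the 277 called results of the rule with another probe set above the filter, 44 had at least 1 pointing the other way and 3 had 1 called in the opposite direction. Agreement was lower over all called genes with another probe set. All probe sets pointed the same way for 68.8% with TNF+IFNg, 65.9% with terbutaline, 72.1% with GW9508 and 69.3% between the compounds. Another probe set was called in the opposite direction for 12.3%, 2.72%, 0.146% and 2.15%. For TMT1A, NR4A1, NR4A3, PLIN2, CXCL11 and HLA-DPB1 the text gives values of their other probe sets.

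Other choices were also made after the data had been seen. These were the dim limit of 34.2 signal units (the 60th percentile), the scalings on the trimmed mean and with the signals as deposited, the genes drawn in the plots, 2 retinoid lists, the tests of explanations named as such in the closing parts, and the way in which the spread of the correlation between the compounds was computed. A group was called dim for a gene when all 3 arrays lay below the limit. The fold is then given as at least the ratio of the bright group's geometric mean to that limit or to the dim group's own signal, whichever was higher on each array, and no fold is given when both groups were dim.

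The procedure was tested on simulated data with 200 of 14056 genes changed. At 2-fold, 66% of the changed genes were recovered with the spread and design of the TNF+IFNg comparison, 80% for terbutaline, 69% for GW9508 and 63% for GW9508 against terbutaline. At 1.5-fold the shares were 53%, 42%, 40% and 46%. The comparisons have groups of equal size and the same median SE, 0.14, so differences between these shares do not rank the comparisons by power. In the data 16.0% to 63.5% of the genes were called, a far larger part than the 200 changed here. With fewer changed genes the Benjamini-Hochberg cutoff is stricter, so the shares do not give the power of the real comparisons. False calls were 4.03%, 6.15%, 5.22% and 5.22% of all calls. Of 200 random lists per comparison, 2, 6, 2 and 1 had a camera p below 0.05. The simulated genes varied independently of each other, so these lists do not test the preset correlation on genes that vary together.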

Results

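HaCaT is a spontaneously immortalised human keratinocyte line. Gene expression was measured in HaCaT cells on 12 Affymetrix HG-U133 Plus arrays in 4 groups of 3 triplicate wells. The groups were unstimulated cells, cells given tumour necrosis factor and interferon gamma together (TNF+IFNg), and cells given the same cytokines after terbutaline or after GW9508. Terbutaline is an agonist of beta-adrenergic receptors and GW9508 is an agonist of the free fatty acid receptors FFAR1 and FFAR4. The treatment protocol in the labels gives 24 h of serum starvation, 5 min with the compound and 24 h with the cytokines for every stimulated group. The sample source names instead give 24 h for TNF+IFNg, 27 h with terbutaline and 30 h with GW9508, so the time of the compound groups is not settled by the labels. The doses are not given in the sources used here.

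The median deposited signal per array ranged from 14.6 to 23.9 intensity units before scaling. Stimulation dominated the data. The first principal component held 71.6% of the variance and placed the unstimulated arrays at -110.0 ± 1.18, the TNF+IFNg arrays at 48.0 ± 1.60, the terbutaline arrays at 24.3 ± 0.62 and the GW9508 arrays at 37.7 ± 0.61 (SD, n = 3 each). Every array correlated more strongly with the arrays of its own group than with those of any other group. The ratio of 3' to 5' actin signal, a sign of RNA quality, was 2.37 ± 0.36 in unstimulated cells, 1.65 ± 0.13 with TNF+IFNg, 1.90 ± 0.27 with terbutaline and 1.64 ± 0.11 with GW9508 (SD, n = 3 each). The corresponding GAPDH ratio lay between 1.02 and 1.04 in all 4 groups. FFAR1 and FFAR4 stayed below the filter on dim probe sets. FFAR1 signals reached at most 1.72 on one probe set and 33.3 on the other, and FFAR4 signals reached at most 18.3, all below the dim limit of 34.2.

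The first comparison asked which genes the cytokines changed. TNF+IFNg raised interferon-response, MHC class II, chemokine and NF-kB genes and lowered mitosis genes. GBP5, an interferon-induced guanylate-binding protein, was dim without the cytokines and at least 363-fold higher with them. The chemokines CXCL11 and CXCL9 were at least 444-fold and at least 469-fold higher. HLA-DRA, an MHC class II chain, was at least 174-fold higher, and the cytokine IL32 was at least 78.2-fold higher. The largest fall among the genes with a signal in both groups was that of MPPED2, which fell by 6.55 on the log2 scale (SE 0.13). TMT1A, dim with the cytokines, was at least 47.9-fold lower on the probe set used, and its other 3 probe sets above the filter lay at log2 fold changes of -1.43, -1.36 and 0.08. Of 14056 genes tested, 4641 were higher and 4284 were lower with TNF+IFNg (limma, Benjamini-Hochberg adjusted p below 0.05), and 2139 and 2067 of these by at least 2-fold.

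The interferon lists moved almost as a whole. Of 35 genes of the type I interferon list tested, 34 rose and 1 was not called, both over all genes and adjusted over the list alone, with a median log2 fold change of 5.33 (camera adjusted p = 1.35e-25). BST2, an antiviral tether, was at least 86.0-fold higher, and IFI27 rose by 8.41 (SE 0.17). In the interferon-gamma list 34 of 35 genes rose and 1 was not called, again the same adjusted over the list alone (camera adjusted p = 8.38e-24). It held IDO1, the tryptophan-degrading enzyme, which went from 33.0 ± 11.5 to 15389 ± 548 signal units (SD, n = 3 each; log2 fold change 8.78, SE 0.15). The transcription factor BATF2 was at least 138-fold higher. All 14 MHC class II genes rose (camera adjusted p = 1.87e-11), with CD74, the invariant chain, at least 135-fold higher and HLA-DPA1 at least 116-fold higher. All 19 MHC class I presentation genes rose too (camera adjusted p = 5.66e-12; adjusted p = 0.0646 with an estimated correlation). Among them the peptide transporter TAP1 rose by 4.57 (SE 0.08) and the immunoproteasome subunit PSMB9 by 3.99 (SE 0.08). For both MHC lists the counts were the same adjusted over the list alone.

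Chemokines and cytokines followed. Of 23 chemokines tested, 19 rose, 2 fell and 2 were not called, with the same counts adjusted over the list alone (camera adjusted p = 2.13e-11). CCL5 (Entrez gene 6352, chromosome 17), a T cell attractant, had a signal of 15.2 ± 1.07 without and 1775 ± 189 with the cytokines (SD, n = 3 each), a rise of at least 51.7-fold. CCL17 (Entrez gene 6361, chromosome 16) went from 6.28 ± 1.74 to 893 ± 45.5, at least 26.1-fold, and CXCL8 was at least 302-fold higher. Of 24 keratinocyte cytokines and growth factors 20 rose, 2 fell and 2 were not called, alike over the list alone (camera adjusted p = 1.38e-09). IL6 went from 29.1 ± 7.43 to 1727 ± 77.9 signal units (SD, n = 3 each; log2 fold change 5.77, SE 0.12), IL1B rose by 5.81 (SE 0.08) and HBEGF by 6.39 (SE 0.07). Of 30 TNF and NF-kB targets 28 rose and 2 were not called, also over the list alone (camera adjusted p = 4.45e-15). They held TNFAIP3, a feedback inhibitor of NF-kB, at a log2 fold change of 6.78 (SE 0.07), the adhesion molecule ICAM1 at 6.42 (SE 0.09) and the prostaglandin synthase PTGS2 at 5.98 (SE 0.12).

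Stress and early-response genes rose with them. Among 20 MAPK and immediate early genes 19 rose and 1 was not called, alike over the list alone (camera adjusted p = 6.26e-11), with FOSL1 at 5.04 (SE 0.11). Of 26 cell death genes 20 rose, 2 fell and 4 were not called, and 21 rose adjusted over the list alone (camera adjusted p = 7.54e-08). CASP1, the inflammasome caspase, rose by 3.24 (SE 0.07). In the list of the unfolded protein response and amino acid stress 28 of 31 genes rose and 3 fell, alike over the list alone (camera adjusted p = 7.18e-09; adjusted p = 0.127 with an estimated correlation). ASNS, asparagine synthetase, rose by 4.21 (SE 0.09).

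All 36 mitosis genes fell, alike over the list alone, with a median log2 fold change of -2.75 (camera adjusted p = 2.27e-16). The DNA topoisomerase TOP2A dropped from 967 ± 71.3 to 41.2 ± 3.82 signal units (SD, n = 3 each; log2 fold change -4.45, SE 0.18), and the kinesin KIF11 was at least 12.5-fold lower. Of 33 S phase genes 28 fell and 5 were not called, alike over the list alone (camera adjusted p = 2.02e-09; adjusted p = 0.0611 with an estimated correlation). They held RRM2 and TYMS, enzymes of nucleotide supply, at -3.28 (SE 0.23) and -3.22 (SE 0.18). Terminal differentiation genes split, with 9 of 25 higher, 7 lower and 9 not called, alike over the list alone, and the list as such was not called (camera adjusted p = 0.477). The cornified envelope protein involucrin (IVL) fell by 5.69 (SE 0.21), while SPRR1A, another envelope precursor, rose by 4.79 (SE 0.09). The mucosal keratin KRT4 was at least 55.5-fold lower and placental alkaline phosphatase (ALPP) at least 45.2-fold lower. Of 24 genes of PPAR and fatty acid oxidation 14 fell, 4 rose and 6 were not called, alike over the list alone (camera adjusted p = 0.0202; adjusted p = 0.362 with an estimated correlation). The medium-chain acyl-CoA dehydrogenase ACADM fell by 1.38 (SE 0.10).

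Of 33 lists tested, 24 were called with the preset correlation, 17 up and 7 down, and 9 of them also with an estimated correlation: type I interferon, interferon gamma, MHC class II, chemokines, cytokines, TNF and NF-kB, MAPK and immediate early, cell death and mitosis. Markers of leukocytes (1 of 6 higher, 5 not called; camera adjusted p = 0.568) and of dermal fibroblasts (2 higher, 2 lower, 3 not called; 3 lower adjusted over the list alone; camera adjusted p = 0.763) were not called. The division into higher and lower genes depended on how the arrays were scaled. Higher genes were 52.0% of the calls, and 31.9% (2707 higher, 5777 lower) with the signals as deposited or 41.5% (3806 higher, 5375 lower) after scaling on the trimmed mean, as the median log2 fold change of all genes moved from 0.05 to -0.30 and -0.14.

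The next comparison set cells given terbutaline before the cytokines against cells given the cytokines alone. With terbutaline, the lists of cytokines, type I interferon, interferon gamma, TNF and NF-kB, cell death, and glycolysis and hypoxia were called lower. Mitosis, MHC class II, PPAR and fatty acid oxidation, and fatty acid synthesis were among the 9 lists called higher. None of these calls held with an estimated correlation (lowest adjusted p = 0.0646 with an estimated correlation). The largest fall among genes with a signal in both groups was that of ACOD1, the enzyme that makes itaconate, from 999 ± 213 to 59.6 ± 6.83 signal units (SD, n = 3 each; log2 fold change -3.98, SE 0.18, adjusted p = 2.30e-10). IL1R2, the decoy receptor for interleukin-1, fell by 2.45 (SE 0.28), and ESM1, an endothelial proteoglycan, was at least 2.83-fold lower. AGR2, a disulfide isomerase of secretory cells, rose from 215 ± 16.4 to 1145 ± 40.1 (SD, n = 3 each; log2 fold change 2.40, SE 0.09). FGF1 was at least 1.94-fold higher, from a dim signal with the cytokines alone. TMT1A was at least 3.31-fold higher on the probe set used and lay at log2 fold changes of 0.19, 0.02 and -0.64 on the other 3. In all, 1905 genes were higher and 1242 lower (limma), 305 and 171 of them by at least 2-fold.

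Most of the always-named chemokines were not called with terbutaline. CCL5 did not pass the test (log2 fold change -0.17, 95% interval -0.46 to 0.12, adjusted p = 0.431), nor did IL6 (-0.32, SE 0.12, adjusted p = 0.0759), CCL20 (-0.34, SE 0.16, adjusted p = 0.136) or CXCL8 (0.04, SE 0.08, adjusted p = 0.792). CCL17 rose slightly, from 893 ± 45.5 to 1198 ± 78.2 signal units (SD, n = 3 each; log2 fold change 0.42, SE 0.13, adjusted p = 0.0304). CXCL9, CXCL10 and CXCL11 were near the top of the signal range in every stimulated group and were not called. The other CXCL11 probe set, further from the top, lay at -0.33, with mean signals of 5604 with TNF+IFNg and 4423 with terbutaline. Of 23 chemokines, 6 fell, 3 rose and 14 were not called (7 fell and 3 rose adjusted over the list alone), and the list was not called (camera adjusted p = 0.09999). CCL8, a monocyte attractant, fell from 2669 ± 261 to 1085 ± 32.3 (log2 fold change -1.29, SE 0.11), CCL7 fell by 1.32 (SE 0.20), and CXCL5, a neutrophil attractant, rose by 0.74 (SE 0.10).

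**Figure D1:**
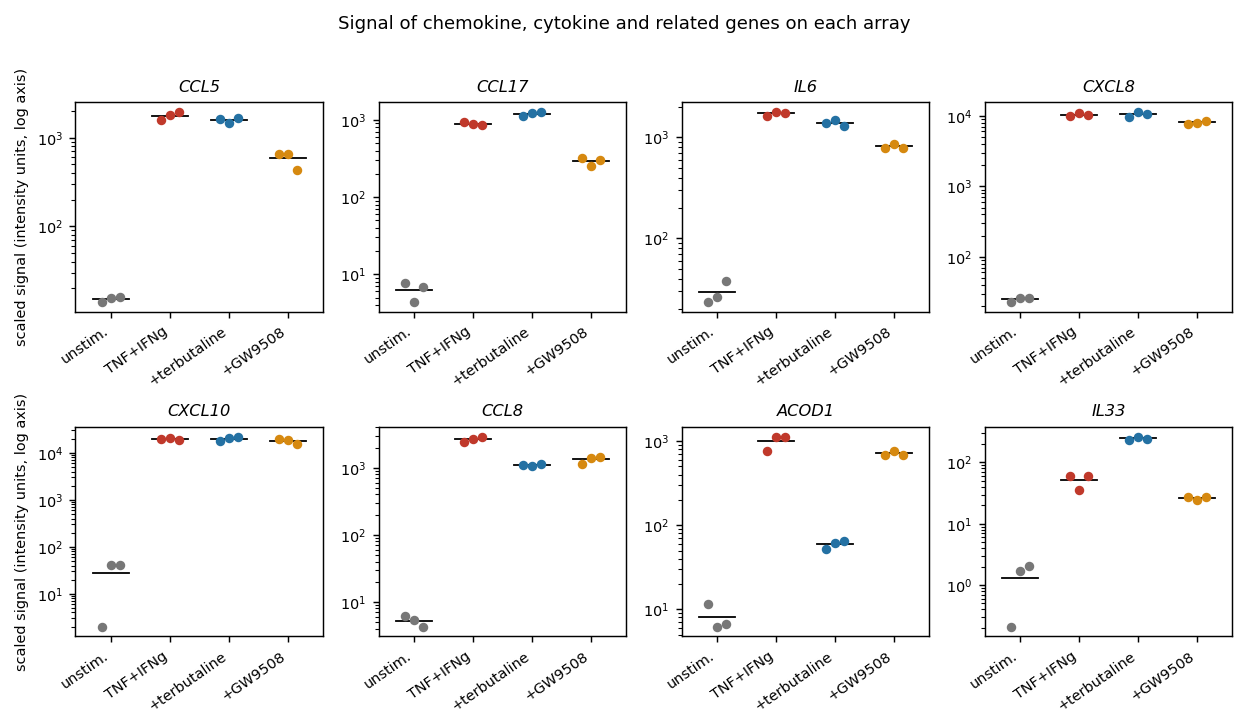
Scaled signal (intensity units, log axis) of 8 genes on the 3 arrays of each group; points are arrays and black lines are group means. GW9508 arrays lie below the TNF+IFNg arrays for CCL5 (means of 583 and 1775), CCL17 (294 and 893) and IL6 (812 and 1727), those of both compounds for CCL8 (1327 with GW9508 and 1085 with terbutaline, against 2669), and terbutaline arrays lie below them for ACOD1 (59.6 and 999) and above them for IL33 (247 and 52.0).

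Of 24 cytokine and growth factor genes, 11 fell, 2 rose and 11 were not called (15 fell and 2 rose adjusted over the list alone; camera adjusted p = 6.04e-06; adjusted p = 0.0646 with an estimated correlation). IL1B fell from 4632 to 1610 signal units on average (log2 fold change -1.52, SE 0.08) and IL36G by 1.60 (SE 0.30), whereas the alarmin IL33 rose by 2.21 (SE 0.26). Among 35 type I interferon genes 15 fell and 20 were not called (16 fell and 1 rose adjusted over the list alone; camera adjusted p = 6.33e-07; adjusted p = 0.211 with an estimated correlation), with MX2 at -0.73 (SE 0.15) and the nucleic acid sensor ZBP1 at -1.68 (SE 0.36). Of 35 interferon-gamma genes 5 fell, 1 rose and 29 were not called, alike over the list alone (camera adjusted p = 0.0309; adjusted p = 0.165 with an estimated correlation). This call was lost after 1 of the other scalings. The falls held the checkpoint ligands CD274 (-1.02, SE 0.09) and PDCD1LG2 (-1.74, SE 0.29). Of 30 TNF and NF-kB targets 13 fell, 2 rose and 15 were not called (15 fell and 3 rose adjusted over the list alone; camera adjusted p = 8.91e-05; adjusted p = 0.226 with an estimated correlation). ICAM1 fell by 0.92 (SE 0.09) and PTGS2 by 1.19 (SE 0.12). In contrast, 8 of 14 MHC class II genes rose, 1 fell and 5 were not called (11 rose adjusted over the list alone; camera adjusted p = 0.00194; adjusted p = 0.165 with an estimated correlation). HLA-DPB1 rose by 1.07 (SE 0.16), with its other probe set at only 0.22, and HLA-DMB rose by 0.99 (SE 0.20). Cell death genes fell more often than they rose, with 11 of 26 lower, 2 higher and 13 not called (13 lower adjusted over the list alone; camera adjusted p = 0.000153; adjusted p = 0.122 with an estimated correlation). The necroptosis kinase RIPK3 fell by 1.10 (SE 0.14).

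Of 36 mitosis genes 27 rose and 9 were not called (30 rose adjusted over the list alone), with a median log2 fold change of 0.83 (camera adjusted p = 1.84e-12; adjusted p = 0.122 with an estimated correlation). CDK1, the mitotic kinase, rose by 1.43 (SE 0.16) and CENPF, a kinetochore protein, by 1.42 (SE 0.17). CDK1 was still at 214 signal units, against 948 in unstimulated cells. The actin 3' to 5' ratio, 1.90 with terbutaline, also lay between those of the TNF+IFNg and unstimulated groups. Among PPAR and fatty acid oxidation genes 11 of 24 rose, 1 fell and 12 were not called (13 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.000211; adjusted p = 0.262 with an estimated correlation), including the mitochondrial carrier UCP2 (2.14, SE 0.18) and the acyl-CoA synthetase ACSL1 (1.05, SE 0.09). Fatty acid synthesis genes rose in 8 of 17 cases, with 1 lower and 8 not called (9 rose adjusted over the list alone; camera adjusted p = 0.00194; adjusted p = 0.339 with an estimated correlation), among them ACSS2 (1.19, SE 0.11) and the desaturase SCD (0.79, SE 0.08). Of 31 glycolysis and hypoxia genes 12 fell, 3 rose and 16 were not called (17 fell adjusted over the list alone; camera adjusted p = 6.04e-06; adjusted p = 0.262 with an estimated correlation). BNIP3, a hypoxia-induced mitophagy receptor, fell by 1.501 (SE 0.10) and the hexokinase HK1 by 0.76 (SE 0.09). Within the NRF2 list 9 of 22 genes rose, 1 fell and 12 were not called, alike over the list alone (camera adjusted p = 0.0116; adjusted p = 0.511 with an estimated correlation), led by the aldo-keto reductases AKR1C2 (1.503, SE 0.10) and AKR1C1 (1.36, SE 0.08).

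Genes of the cAMP and CREB list went both ways with terbutaline. Of 23 tested, 8 rose, 3 fell and 12 were not called (10 rose and 6 fell adjusted over the list alone), and the list was not called (camera adjusted p = 0.09999). The clock gene PER2 rose from 426 ± 24.2 to 1090 ± 59.7 signal units (SD, n = 3 each; log2 fold change 1.35, SE 0.09, adjusted p = 1.00e-08) and the orphan nuclear receptor NR4A1 by 1.29 (SE 0.25). The other 2 NR4A1 probe sets lay at 0.63 and -0.54, the latter with mean signals of at most 15.7 units in these groups. NR4A3, of the same family, was dim with the cytokines alone and at least 2.003-fold higher on the probe set used. Its other 2 probe sets lay at 1.88 and -0.20, with mean signals of at most 27.4 and 11.8 units in these groups. The early-response transcription factor EGR3, of the MAPK list, rose by 1.74 (SE 0.17). AKAP12, a kinase anchor, fell by 1.20 (SE 0.23). In the list of beta-adrenergic and free fatty acid receptors and signalling 3 of 15 genes rose, 2 fell and 10 were not called, alike over the list alone (camera adjusted p = 0.672), with the adenylate cyclase ADCY7 at -0.73 (SE 0.09).

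Of the 33 lists 15 were called for terbutaline with the preset correlation, 9 up and 6 down, and fry, which asks whether a list's own genes moved on balance one way, called 20. When the probe sets of each gene were averaged 1943 genes were called in place of 3147, and with the signals as deposited 1766.

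The GW9508 comparison again used the cells given the cytokines alone as reference. With GW9508, several chemokines and cytokines raised by TNF+IFNg were lower, and so were immediate early and cAMP-linked genes, while 12 of 24 genes of PPAR and fatty acid oxidation were higher, in a list whose call was lost with an estimated correlation (adjusted p = 0.272 with an estimated correlation). CCL5 went from 1775 ± 189 to 583 ± 134 signal units (SD, n = 3 each; log2 fold change -1.62, SE 0.14, adjusted p = 7.48e-07) and CCL17 from 893 ± 45.5 to 294 ± 35.9 (-1.60, SE 0.13, adjusted p = 5.79e-07). IL6 went from 1727 ± 77.9 to 812 ± 45.1 (-1.09, SE 0.12, adjusted p = 1.64e-05). All 3 remained far above the unstimulated level. The largest rise among genes with a signal in both groups was that of DHRS3, a retinaldehyde reductase, from 124 ± 13.4 to 633 ± 50.2 (2.32, SE 0.10, adjusted p = 2.08e-10). Its signal was 1180 ± 109.9 without the cytokines and 290.1 ± 11.2 with terbutaline.

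In all, 1804 genes were higher and 446 lower with GW9508 (limma), but only 90 and 62 of them by at least 2-fold. The median log2 fold change of all genes was 0.10, and relative to it CCL5 stood at -1.73, CCL17 at -1.70 and IL6 at -1.19. Higher genes made up 80.2% of the calls, against 59.1% (1064 higher, 735 lower) after quantile normalization, 57.5% (1035 higher, 764 lower) on the trimmed mean and 91.5% (1534 higher, 142 lower) with the signals as deposited, which moved the median of all genes to 0.02, 0.00 and 0.20. The count was 1409 genes without TNF+IFNg replicate 3, 1499 without GW9508 replicate 3, 1129 when probe sets were averaged and 1467 without probe sets shared between transcripts.

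Of 23 chemokines 10 fell, 2 rose and 11 were not called, alike over the list alone (camera adjusted p = 1.80e-08). Besides CCL5 and CCL17 the fractalkine gene CX3CL1 fell by 1.20 (SE 0.23), CCL20 by 0.61 (SE 0.16) and CXCL8 by 0.36 (SE 0.08). CCL8, named here after its value was seen, lay at -1.01 (SE 0.11). CXCL9 (0.05, SE 0.32, adjusted p = 0.940), CXCL10 (-0.16, SE 0.50, adjusted p = 0.881) and CXCL11 (-0.11, SE 0.23, adjusted p = 0.788) did not pass the test. The other CXCL11 probe set lay at -0.17, with mean signals of 5604 with TNF+IFNg and 4987 with GW9508. CXCL10 signals were 19935 ± 1016 and 17954 ± 1917 (SD, n = 3 each), near the top of the range. The interval for CXCL10 (-1.21 to 0.90) was wide because the spread is pooled over all 12 arrays, including unstimulated ones at 27.7 ± 22.3. With only the arrays of the groups compared, the adjusted p was 0.617 for CXCL9, 0.186 for CXCL10 and 0.219 for CXCL11. Of 24 cytokines and growth factors 8 fell and 16 were not called, alike over the list alone (camera adjusted p = 8.65e-07), among them IL24 at -1.29 (SE 0.26) and epiregulin (EREG) at -0.73 (SE 0.15). Of 35 interferon-gamma genes 4 fell and 31 were not called, alike over the list alone (camera adjusted p = 8.65e-07). The shift was small, with a list median of -0.14, and CD274 had the largest fall, 0.62 (SE 0.09). Of 30 TNF and NF-kB targets 9 fell, 1 rose and 20 were not called (12 fell adjusted over the list alone; camera adjusted p = 1.80e-08; adjusted p = 0.0586 with an estimated correlation), with PTGS2 at -0.84 (SE 0.12) and TRAF1 at -0.71 (SE 0.14).

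Of 23 genes of the cAMP and CREB list 15 fell, 1 rose and 7 were not called (17 fell adjusted over the list alone), and the median log2 fold change was -0.51 (camera adjusted p = 5.63e-17). NR4A1 fell by 1.40 (SE 0.25), the phosphatase DUSP1 fell by 1.253 (SE 0.10) and the stress factor ATF3 fell by 0.91 (SE 0.10), and the 1 that rose, named here after its value was seen, was AKAP12 (0.86, SE 0.23). The other 2 NR4A1 probe sets lay at -0.39 and 0.16. Of 20 MAPK and immediate early genes 10 fell, 1 rose and 9 were not called, alike over the list alone (camera adjusted p = 1.98e-07), with FOS at -0.96 (SE 0.20) and EGR3 at -0.93 (SE 0.17). Of 10 glucocorticoid targets 6 fell and 4 were not called (7 fell adjusted over the list alone; camera adjusted p = 2.74e-10). These were led by DUSP1, the kinase SGK1 (-1.24, SE 0.09) and the thioredoxin-binding protein TXNIP (-0.98, SE 0.07). TNF+IFNg had raised the glucocorticoid list (median log2 fold change 1.52, camera adjusted p = 0.00312) and the cAMP and CREB list (0.80, camera adjusted p = 0.00300). Neither of those rises was called with an estimated correlation. Of the 33 lists 20 were called for GW9508 with the preset correlation, 6 up and 14 down. The type I interferon list was also lower (median log2 fold change -0.13, camera adjusted p = 1.87e-07). So were MHC class II (-0.15, adjusted p = 0.00496) and the unfolded protein response and amino acid stress (-0.11, adjusted p = 0.000164). Mitosis was higher (0.39, adjusted p = 0.00372). These named calls were lost with an estimated correlation. The 6 lists that kept their call with an estimated correlation were cAMP and CREB, glucocorticoid, chemokines, interferon gamma, cytokines, and MAPK and immediate early.

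**Figure D2:**
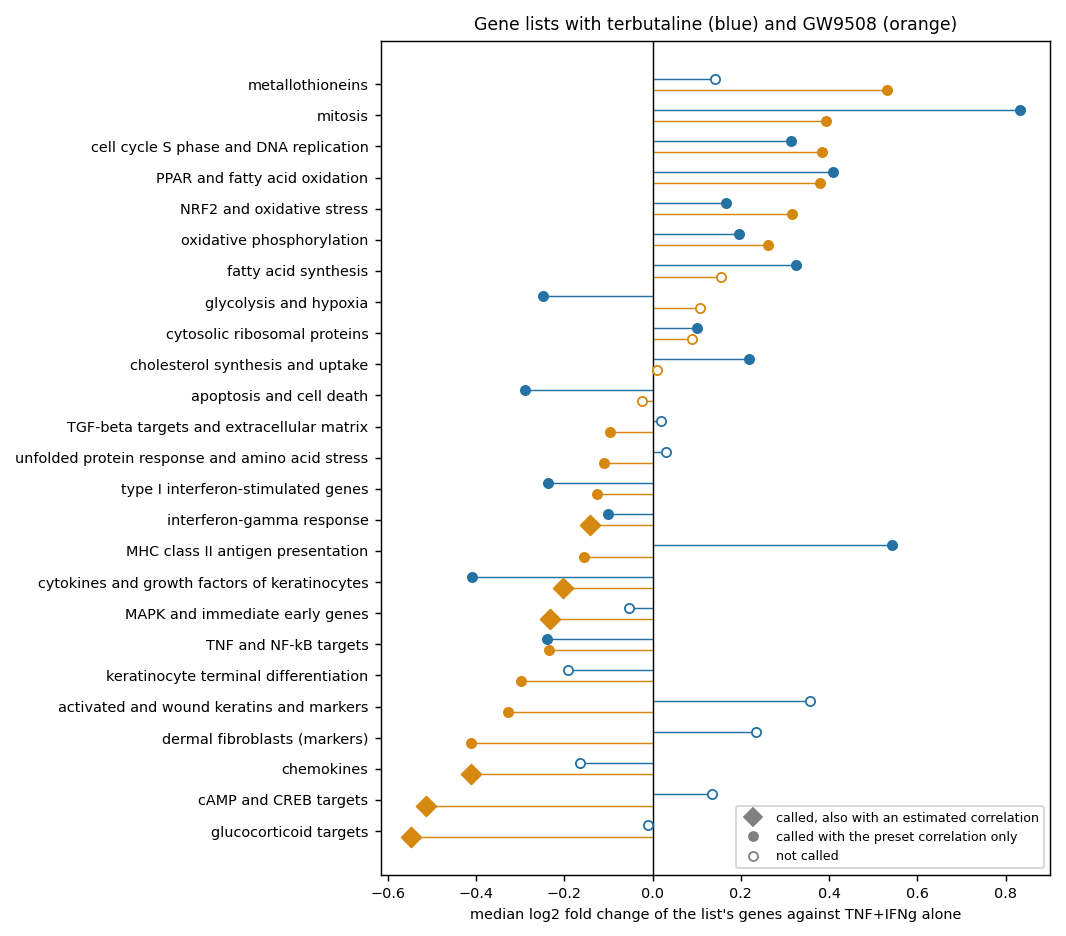
Median log2 fold change of the genes of each list against TNF+IFNg alone, for the lists called with terbutaline (blue) or GW9508 (orange); filled symbols were called, diamonds also with an estimated correlation, and open circles were not called. The cAMP and CREB list lies at -0.51 with GW9508 and 0.13 with terbutaline, the mitosis list at 0.39 and 0.83, and the MHC class II list at -0.15 and 0.54.

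Of 24 genes of PPAR and fatty acid oxidation 12 rose, 2 fell and 10 were not called (15 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.00372; adjusted p = 0.272 with an estimated correlation). The lipid droplet protein PLIN2 rose from 157 ± 21.4 to 591 ± 115 signal units (SD, n = 3 each; log2 fold change 1.88, SE 0.13, adjusted p = 9.63e-08). Its other probe set lay at 0.24, with mean signals of 25.8 and 16.3 units. The rises also held ANGPTL4, an inhibitor of lipoprotein lipase, at 1.67 (SE 0.29). The 2 that fell were FABP3 (log2 fold change -1.23) and TXNIP (-0.98). The other lipid lists were not called. Of 19 cholesterol genes 2 fell and 17 were not called, alike over the list alone (camera adjusted p = 0.0509), and this list stayed without a call in 16 of the 27 other settings. Of 17 fatty acid synthesis genes 4 rose, 1 fell and 12 were not called, alike over the list alone (camera adjusted p = 0.927). Of 10 LXR targets 1 rose and 9 were not called, with 0 called over the list alone (camera adjusted p = 0.297). Among metallothioneins 6 of 7 rose and 1 was not called (7 rose adjusted over the list alone; camera adjusted p = 1.59e-06; adjusted p = 0.0985 with an estimated correlation), with MT1H at 0.81 (SE 0.09). Among oxidative phosphorylation genes 15 of 34 rose and 19 were not called (22 rose adjusted over the list alone; camera adjusted p = 1.98e-07; adjusted p = 0.299 with an estimated correlation), with ATP5MC1 at 0.66 (SE 0.12). Of 33 S phase genes 12 rose and 21 were not called (14 rose adjusted over the list alone; camera adjusted p = 5.57e-06; adjusted p = 0.145 with an estimated correlation), with PCNA, the replication clamp, at 0.79 (SE 0.09). Of 22 NRF2 genes 10 rose and 12 were not called (12 rose adjusted over the list alone; camera adjusted p = 0.000736; adjusted p = 0.299 with an estimated correlation), with AKR1C3 at 1.01 (SE 0.14) and GSR, glutathione reductase, at 0.66 (SE 0.12).

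Of 25 keratinocyte differentiation genes 6 fell, 3 rose and 16 were not called (8 fell and 4 rose adjusted over the list alone; camera adjusted p = 0.000114; adjusted p = 0.0972 with an estimated correlation). Transglutaminase 1 (TGM1), which crosslinks the cornified envelope, fell from 898 ± 17.7 to 265 ± 22.8 signal units (SD, n = 3 each; log2 fold change -1.75, SE 0.09, adjusted p = 2.04e-09), and the protease KLK5 rose by 1.05 (SE 0.12). Of 13 activated and wound markers 5 fell, 3 rose and 5 were not called (6 fell adjusted over the list alone; camera adjusted p = 0.00246; adjusted p = 0.0985 with an estimated correlation). Keratin 16 (KRT16) fell by 1.53 (SE 0.17) and SERPINB4 rose by 1.28 (SE 0.21). The potassium channel gene KCNB2, called higher, was dim in both groups, so no fold is given. TNFAIP6, a hyaluronan-binding protein, fell by 2.27 (SE 0.35) and the decoy receptor TNFRSF11B by 1.95 (SE 0.16). Dermal fibroblast markers were called lower (camera adjusted p = 0.0291; adjusted p = 0.266 with an estimated correlation) with 1 of 7 genes called lower and 6 not called, alike over the list alone, and this call was lost after 2 of the other scalings. In the list of beta-adrenergic and free fatty acid receptors and signalling 2 of 15 genes rose and 13 were not called, alike over the list alone (camera adjusted p = 0.1803).

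GW9508 and terbutaline were then compared with each other in stimulated cells. With GW9508, 14 of 23 cAMP and CREB genes, 11 of 14 MHC class II genes, 14 of 36 mitosis genes and 11 of 19 cholesterol genes were lower than with terbutaline. IL1B, ACOD1 and 19 of 31 glycolysis and hypoxia genes were higher. Of these lists cAMP and CREB kept its call with an estimated correlation (adjusted p = 0.0431 with an estimated correlation), while MHC class II, mitosis, cholesterol and glycolysis did not (adjusted p from 0.0646 to 0.348). CCL17 was lower by a log2 fold change of -2.02 (SE 0.13, adjusted p = 6.77e-09), CCL5 by -1.45 (SE 0.14, adjusted p = 5.20e-07) and IL6 by -0.77 (SE 0.12, adjusted p = 0.000147). ACOD1 was higher by 3.51 (SE 0.18, adjusted p = 3.98e-10) and IL1B by 1.59 (SE 0.08, adjusted p = 3.30e-10). Of 14056 genes, 2581 were higher and 1435 lower with GW9508 (limma), 228 and 313 by at least 2-fold.

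Of 23 cAMP and CREB genes 14 were lower, 1 higher and 8 not called (2 higher adjusted over the list alone; camera adjusted p = 5.32e-10; adjusted p = 0.0431 with an estimated correlation), and this was the 1 list of the comparison whose call held both ways. NR4A3, dim with GW9508, was at least 2.003-fold lower on the probe set used and lay at log2 fold changes of -2.16 and 0.04 on its other 2. NR4A1 differed by -2.69 (SE 0.25), with its other 2 probe sets at -1.01 and 0.70, and AKAP12 by 2.06 (SE 0.23). DUSP1, which the glucocorticoid and MAPK lists share, differed by -1.54 (SE 0.10). Of 14 MHC class II genes 11 were lower and 3 not called (11 lower and 2 higher adjusted over the list alone; camera adjusted p = 5.44e-06; adjusted p = 0.0646 with an estimated correlation), with HLA-DPB1 at -1.16 (SE 0.16). Its other probe set lay at -0.54. Of 36 mitosis genes 14 were lower and 22 not called, alike over the list alone (camera adjusted p = 1.59e-06; adjusted p = 0.319 with an estimated correlation), with NUSAP1 at -1.14 (SE 0.11). Of 19 cholesterol genes 11 were lower and 8 not called (12 lower adjusted over the list alone; camera adjusted p = 2.13e-06; adjusted p = 0.348 with an estimated correlation), with EBP, a sterol isomerase, at -0.49 (SE 0.09). Of 31 glycolysis and hypoxia genes 19 were higher, 2 lower and 10 not called (20 higher adjusted over the list alone; camera adjusted p = 3.54e-05; adjusted p = 0.348 with an estimated correlation), with BNIP3 at 1.57 (SE 0.10) and PFKFB3 at 1.01 (SE 0.12). Of 23 chemokines 7 were lower, 2 higher and 14 not called (8 lower and 4 higher adjusted over the list alone; camera adjusted p = 0.0352; adjusted p = 0.348 with an estimated correlation). Keratin 16 (KRT16) differed by -1.89 (SE 0.17) and the antimicrobial S100A8 by -2.02 (SE 0.24).

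Of the 33 lists 16 were called in this comparison, 4 higher and 12 lower with GW9508. Higher genes were 64.3% of the calls, against 47.5% (1855 higher, 2049 lower) after quantile normalization, 43.9% (1762 higher, 2253 lower) on the trimmed mean and 82.9% (3103 higher, 641 lower) with the signals as deposited. The chemokine call was lost in 6 of the 27 other settings tried, and averaging probe sets left 2485 calls in place of 4016.

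**Figure D3:**
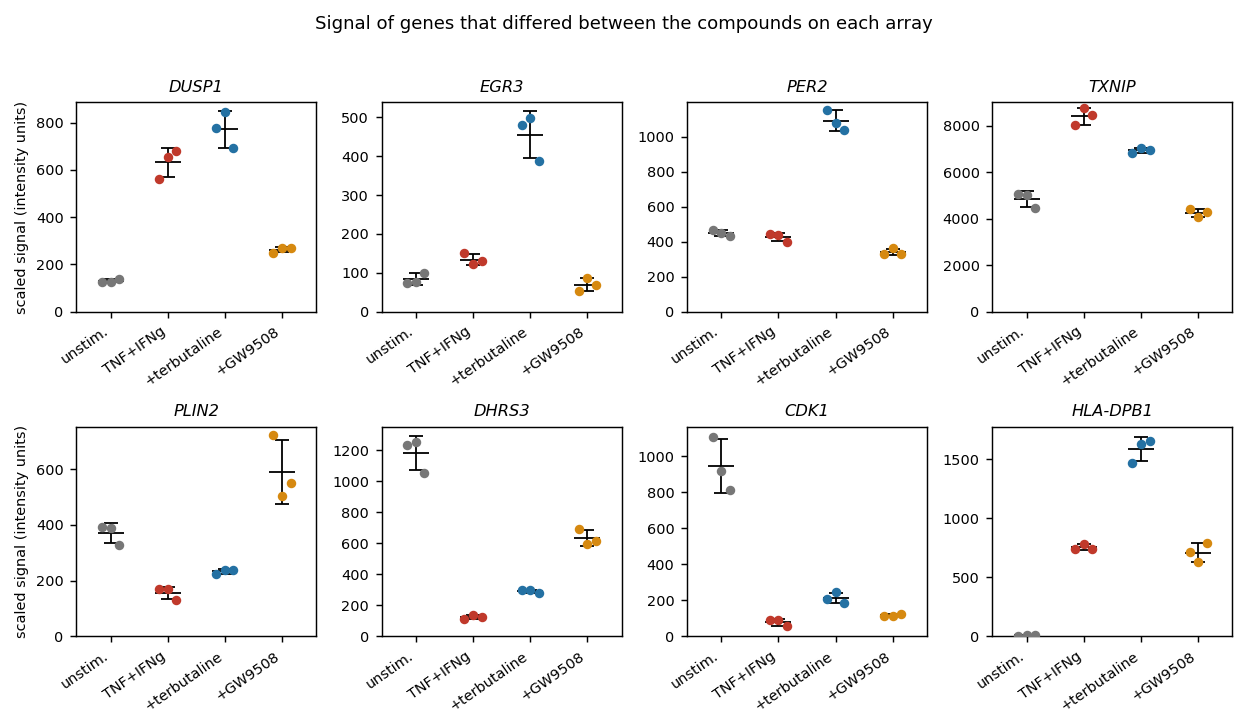
Scaled signal (intensity units, linear axis from 0) of 8 genes on the 3 arrays of each group; points are arrays, horizontal bars are means and error bars are 1 SD. EGR3 and PER2 were highest with terbutaline (means of 456 and 1090), PLIN2 was highest with GW9508 (591), and HLA-DPB1 averaged 754 with TNF+IFNg, 1585 with terbutaline and 708 with GW9508.

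The last comparison asked how far each compound opposed the cytokines. The source names give both compound groups later times, 27 h and 30 h, than the 24 h of TNF+IFNg. Time and compound therefore cannot be told apart in these counts and slopes. Of the 4641 genes raised by TNF+IFNg, 1100 (23.7%) were lower with terbutaline and 339 (7.30%) with GW9508, and 210 and 380 were higher. Of the 4284 genes lowered by TNF+IFNg, 1497 (34.9%) were higher with terbutaline and 1096 (25.6%) with GW9508, and 37 and 53 were lower. Higher genes were 80.2% of all GW9508 calls, a share that depended on the scaling, so the 1096 may depend on it too. ICAM1 and IL1B were among the raised genes that terbutaline lowered, CCL5, CCL17 and IL6 among those that GW9508 lowered, and CCL8 among those that both lowered. Lists of these sizes drawn independently would share 410 genes in place of the 1100 and 147 in place of the 339. For the lowered genes they would share 581 in place of the 1497 and 550 in place of the 1096. Both steps share the TNF+IFNg arrays. Unchanged compound groups simulated with a shared, redrawn TNF+IFNg group gave overlaps of 0 genes in every simulation, so these counts do not show how much comes from the shared arrays. Across genes, the slope of the compound effect on the TNF+IFNg effect was -0.179 for terbutaline and -0.0990 for GW9508, against -0.0183 and -0.0190 in the simulated unchanged groups. The GW9508 count of 339 was 525 after quantile normalization, 537 on the trimmed mean, 100 with the signals as deposited and 220 when probe sets were averaged. It was 207 without TNF+IFNg replicate 2 and 218 without TNF+IFNg replicate 3. The terbutaline count of 1100 was 635 with the signals as deposited and 723 when probe sets were averaged.

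The compounds raised 575 genes in common and lowered 134 in common, where independent lists would share 244 and 39.4. They moved 82 genes in opposite directions with terbutaline higher and 133 with terbutaline lower, where independent lists would share 60.4 and 159. Across genes, which are not independent replicates, the effects of the compounds correlated at r = 0.325, below the 0.503 that simulated unchanged groups gave through the shared TNF+IFNg arrays. The covariance was 0.0554 against a simulated 0.0358, a difference of 0.0196. With 3 TNF+IFNg arrays the controls could not be split into parts of at least 2, and part of the excess overlap may come from the shared arrays. The later labelled times of both compound groups may also contribute, and they cannot be told apart from the compounds. PTGS2, SGK1, CCL8, CCL7, CX3CL1 and IL24 fell with both compounds. PLIN2 was higher with both on the probe set used, but with terbutaline its other probe set lay at -0.50.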

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

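The tests of the scaling behind the excess of higher genes, of dim probe sets in the cAMP and CREB list and of the actin ratio were chosen only after the result was seen, and so was the adjustment of the camera p-values over the 2 subsets of that list.

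The compounds called 215 genes in opposite directions with a called difference between them. They were looked at again because the compounds moved them apart. Genes called in opposite directions against the same TNF+IFNg arrays nearly have to pass a test of the difference, so that test adds little. Terbutaline was higher for 82 of them and lower for 133, where independent lists would share 60.4 and 159. Among these 215 genes, with uncharacterised symbols passed over, the largest fitted log2 differences between GW9508 and terbutaline (limma) follow. They were 3.85 for DACT1, -3.68 for NR4A3, -3.22 for TCIM, -3.08 for IL33, 2.92 for HAS2 and -2.92 for TNFRSF11B. NR4A3 lay at -2.16 and 0.04 on its other 2 probe sets. As DACT1 was dim with terbutaline and NR4A3 and IL33 with GW9508, their folds are bounds of at least 4.76, 2.003 and 7.21. Their places in this order are therefore not settled. Probe sets that are unnamed here also changed. Of 4749 tested, 735 were higher and 1032 lower with TNF+IFNg, 233 higher and 155 lower with terbutaline, 124 higher and 44 lower with GW9508, and 231 higher and 188 lower with GW9508 against terbutaline.

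More genes were higher than lower with GW9508, 80.2% of the calls. The share was 59.1% after quantile normalization and 57.5% on the trimmed mean, but 83.3% with each array centred on its median and 91.5% as deposited. Quantile normalization fixes much of the balance it was to test, and the other scalings fall on both sides of the bounds of 60% and 70%, so scaling stays open. The weighing was first dropped and then restored with its bounds as first written, and the other scalings were added to it after their values were seen. No biological explanation for the excess was tested.

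The cAMP and CREB list was lower with GW9508. TNF+IFNg had raised it (median log2 fold change 0.80, camera adjusted p = 0.00300), a call lost with an estimated correlation. The highest camera adjusted p over 4 other scalings was 1.04e-14 with the direction kept. Scalings that shift all genes of an array nearly alike cancel when a list is compared with other genes, so they could hardly change this call. Quantile normalization does not shift all genes alike. It gave a camera adjusted p = 8.91e-15, which argues against scaling. The 17 members in no other list held 10 lower and 1 higher gene (camera in limma, adjusted p = 1.89e-11 over the 2 subsets). The 20 members with a signal in both groups held 13 lower and 1 higher (camera adjusted p = 4.05e-16). As the list of 23 was already called on these arrays, small p-values were likely beforehand. The lower genes that remain argue against dim probe sets and genes named in other lists as the only source. Early-response genes that no other list names were not removed, so a wider early-response programme stays open. A response of the cells to GW9508 is consistent with these values as a hypothesis found and tested on the same arrays. Whether the fall is part of a smaller response to the cytokines was not tested. The labelled time, which differs between the groups, stays open.

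Terbutaline arrays lay nearer to the unstimulated arrays than GW9508 arrays did. With no array in common, the slope of terbutaline minus GW9508 on TNF+IFNg minus unstimulated was -0.0804 (jackknife SE 0.00462), which argues against the shared TNF+IFNg arrays. The terbutaline arrays spread over 1.38% of what their actin ratios predict from the other groups, but that slope across groups also carries the effect of the cytokines. The test therefore excludes nothing. Array by array, the terbutaline arrays had actin ratios of 1.65, 2.19 and 1.86 and lay at 23.6, 24.4 and 24.8 on the first component. The GW9508 arrays had ratios of 1.57, 1.76 and 1.58 and lay at 37.2, 37.7 and 38.4. Position did not follow the ratio within either group, which argues against the actin ratio for these arrays. The source names give 27 h and 30 h to these groups and they share 0 times, so the time and the compound cannot be told apart.

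For each comparison the 6 arrays make 10 splits, too few for a share below 0.1, and 1 split, the real one, gave as many calls. The real counts were 8925, 3147, 2250 and 4016 for TNF+IFNg, terbutaline, GW9508 and GW9508 against terbutaline. The highest of the other splits gave 0, 1, 0 and 2 genes with limma, and at most 267, 602, 744 and 785 at an unadjusted p below 0.05. Every other split mixes arrays of both groups, which puts the group difference into the spread. Their low counts were thus built in and add no support to the real counts.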

How the results depend on the processing

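The signals as deposited and the scaling on the trimmed mean were chosen only after seeing the data; the other settings were planned. Of 13850 values of named genes under other settings, 13328 kept direction and side of the threshold, 490 were weaker, 5 stronger and 27 reversed.

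Requiring a 2-fold change left 4206, 476, 152 and 541 genes for TNF+IFNg, terbutaline, GW9508 and GW9508 against terbutaline, and 39 and 128 raised genes lowered by GW9508 and by terbutaline, since the threshold is stricter. An estimated correlation left 9, 0, 6 and 1 lists called by camera. Averaging probe sets gave 1943 genes for terbutaline, 1129 for GW9508, 2485 between the compounds, and 220 and 723 raised genes lowered by GW9508 and terbutaline. Without probe sets shared between transcripts there were 1467 genes for GW9508, 7 lists for terbutaline and 7 between the compounds, with fewer genes tested. Testing all probe sets alone gave 17940, 5040 and 6221 calls for TNF+IFNg, terbutaline and the compounds against each other, and 1789 raised ones lowered by terbutaline, with more features tested. Signals as deposited gave 1766 genes for terbutaline, and 100 and 635 raised genes lowered by GW9508 and terbutaline. Raised genes lowered by GW9508 numbered 525 after quantile normalization and 537 on the trimmed mean. The correlation of the compounds' effects, 0.325, was 0.356 with no offset, 0.304 with the offset doubled, 0.351 with a floor, 0.394 with no filter, 0.237 with a stricter filter, 0.361 without shared probe sets and 0.374 over all probe sets. Its spread of 0.0178 was recomputed from deviations within groups after a first version had shown no move. Where no construction is named, the cause was not tested.

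Leaving out 1 array at a time gave 8421 to 8995 genes for TNF+IFNg, 2442 to 3409 for terbutaline, 1409 to 2548 for GW9508 and 3287 to 4230 between the compounds. The 1409 came without TNF+IFNg replicate 3, and without GW9508 replicate 3 there were 1499. Raised genes lowered by GW9508 ranged from 207 without TNF+IFNg replicate 2 to 388, with 218 without TNF+IFNg replicate 3, and those lowered by terbutaline from 783 to 1205. The correlation ranged from 0.294 to 0.396, and called lists from 23 to 24, 14 to 17, 19 to 23 and 13 to 17. With the replicate number as a replicate block there were 8945, 3172, 2216 and 4042 genes. Arrays of the same number in different groups correlated at -0.0532 to 0.0832 in their deviations and those of other numbers at -0.0672 to 0.0558, so the numbers do not pair the arrays.

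Reversed values of single genes follow. NR4A3 lay at -0.29 for terbutaline and 0.0485 between the compounds with no offset and with a floor. It lay at -0.24 and 0.04 without TNF+IFNg replicate 1, -0.19 and 0.04 without TNF+IFNg replicate 2, -0.53 and 0.36 without terbutaline replicate 1, and -0.11 for terbutaline without terbutaline replicate 3, within ranges of -0.53 to 2.11 and -3.74 to 0.36. Averaging probe sets put ADCY9 at -0.28 for terbutaline, NDUFA2 at -0.28, COX7B at -0.00369 and P4HA1 at -0.20 for GW9508, and MCM6 at -0.00301, COX7B at -0.27 and TAPBP at 0.0513 between the compounds. Without shared probe sets CREM lay at -0.12 and TMT1A at 0.0788 for TNF+IFNg, TMT1A at -0.64, CFLAR at 1.03 and TAGLN at 0.0512 for terbutaline, NDUFA2 at -0.52 for GW9508, and TAGLN at -0.71, NDUFA2 at -1.06 and HSPB8 at 0.41 between the compounds. In the last 2 settings, and for NR4A3 in all the settings named, another probe set of the gene enters. Dim signals are a further limit, as 1181 called genes of TNF+IFNg were dim in 1 group and 275 in both.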

Other observations

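The retinoid lists, the test of their suppressed genes, the test of scaling on DHRS3 and CYP26B1, the adjustment over the 2 retinoid lists and the naming of CYP26B1 were chosen only after values were seen.

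Antimicrobial and stress lists outside the comparisons above gave mixed values. Of 8 antimicrobial genes 6 rose, 1 fell and 1 was not called with TNF+IFNg, alike adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.188 with an estimated correlation). The defensin DEFB1 fell by 3.05 (SE 0.20) while the others that rose included the protease inhibitor PI3. With terbutaline 4 of the 8 rose, 1 fell and 3 were not called (5 rose adjusted over the list alone; camera adjusted p = 0.0587). S100A8 rose by 1.69 (SE 0.24), and the 1 that fell was the ribonuclease RNASE7, at -1.60 (SE 0.15). With GW9508 2 rose, 3 fell and 3 were not called, alike over the list alone (camera adjusted p = 0.449), with the siderophore-binding protein LCN2 at 1.13 (SE 0.10). Of 21 p53 targets 11 rose, 7 fell and 3 were not called with TNF+IFNg (12 rose adjusted over the list alone), and the list was not called (camera adjusted p = 0.183), although CDKN1A, a cell cycle inhibitor, rose by 3.28 (SE 0.07). All of the 6 LXR targets called with TNF+IFNg, of 10 tested, fell, alike over the list alone (camera adjusted p = 0.0232; adjusted p = 0.292 with an estimated correlation), a call that was lost after 1 other scaling. SMPDL3A fell by 3.05 (SE 0.11). With GW9508 the mitochondrial chaperonin HSPE1 rose by 0.92 (SE 0.09), in a heat shock list that was not called (3 of 15 higher, 1 lower, 11 not called, alike over the list alone; camera adjusted p = 0.113).

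DHRS3 (log2 fold change 2.32) and CYP26B1, a retinoic acid hydroxylase (1.77, SE 0.11), were both higher with GW9508, and a retinoid-type response was tested as a hypothesis. DHRS3 had fallen by 3.21 (SE 0.10) with TNF+IFNg and was also higher with terbutaline (1.20, SE 0.10), so its rise was shared by both compounds and went back towards the unstimulated level. CYP26B1 had risen by 2.09 (SE 0.11) with TNF+IFNg and was not called with terbutaline (-0.18, SE 0.11, adjusted p = 0.257 by limma). The hypothesis predicted that other retinoid-induced genes would be higher. Of 9 tested 3 were higher (KRT19, KRT13 and STRA6) and 0 lower by limma, with a camera adjusted p = 0.352 over the 2 lists, and a list median of 0.30 against 0.10 for all genes. The bound written before that result was seen took a p of 0.05 or more as evidence against the hypothesis. That bound was wrong, since a missed threshold over 9 genes whose median lies on the predicted side excludes nothing, and this part stays open. Of 7 retinoid-suppressed epidermal genes 2 were lower (SPRR1B and IVL), with a camera adjusted p = 0.00986 (adjusted p = 0.0401 with an estimated correlation). All 7 are also in the terminal differentiation list, which was called lower with GW9508, so this test restates that call and decides nothing about the hypothesis. The highest adjusted p of the 2 genes over 4 other scalings was 1.01e-07, which argues against scaling. Neither retinoid test decides, and the hypothesis stays open.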
